A study of Homo sapiens with 6 samples.

How the data were processed

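RNA sequencing had been run on iCell cardiomyocytes from 6 transfected samples, 3 with a FAM13B siRNA and 3 with a scrambled siRNA, from total RNA extracted with TRIzol and a column kit, per the labels' protocols. The authors deposited 1 table of log2 values, with a row per NCBI Entrez Gene identifier and a column per sample, in which genes of low expression had already been left out. The column names are those of sorted alignment files, per the file headers, and limma is named in the submitters' processing notes. The aligner, the counting tool, the strand setting and the genome build are not given in the sources used here. The column names read KO where the labels read knockdown, and the columns were matched to samples by arm and replicate number.

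The deposited log2 values run from -3.15 to 15.57. In each column, 2 raised to the value was a whole number of reads plus 0.5 times a fixed step, in 100.00% of values within 0.01 reads, which is the form of a log2 CPM as limma's voom writes it. The step gives the effective library size, from 61716844 to 91397739 reads, and the reads held in the table, 63572874, 62919022 and 90027213 in FAM13B siRNA replicates 1, 2 and 3 and 82953418, 82938404 and 74386805 in scrambled replicates 1, 2 and 3. The median gene has 2095 to 3034 reads in a sample, so that counting error is small beside the spread between samples for most genes. The normalization behind the effective library sizes is the authors' own. Reads from overlapping or antisense genes cannot be told apart without the strand setting.

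The replicates were compared before averaging. Scrambled replicates 1 and 2 had a chi-square of their reads of 0.00541 per degree of freedom and equal reads in 7938 of 11017 genes, whereas the other 5 pairs of the same arm gave 58.8 to 277. These columns were averaged and counted as 1 sample, which leaves 3 samples against 2 and 3 residual degrees of freedom. This was decided before the counts of changed genes were compared. The design set before the data were examined had 6 separate samples, and that fit is given as an alternative. The labels speak of biological replicates, and nothing further says that they came from separate cultures, so that p-values measure the spread between these samples.

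Genes with a log2 value over 0 in at least 3 samples were kept, which dropped 1 gene (SNORD3B-1) and left 11016. Differences were tested two-sided with limma 3.58.1 in R 4.3.3, using lmFit and eBayes with a variance trend and no covariate, on the log2 values as deposited. Adjusted p-values follow Benjamini-Hochberg over all genes, with a threshold of 0.05, and intervals cover 95%. Gene symbols came from a RefSeq table of GRCh38.p14, which matched 10898 of 11017 identifiers and left 119 without a symbol. Before the data were examined, 43 gene lists were fixed for cardiac function, signalling, stress, metabolism and other cell types. The 40 lists with at least 3 measured members were tested with camera at a preset correlation of 0.01, adjusted over the lists. Markers of pluripotency, skeletal muscle and liver had 1, 2 and 1 measured members and were not tested.

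The genes named in the text follow a rule set before the data were examined. It takes the FAM13 family. It takes up to 10 rising and 10 falling genes with the largest change among those past the threshold, whose arms do not overlap and whose mean is at or above the median of tested genes. It takes the 4 members with the smallest p in each list past the threshold, and 8 genes of cardiac identity. The rule gave 3 rising and 10 falling genes, and not every gene it gave is printed. The other 12 genes past the threshold, and 27 genes past it only over a list alone, were chosen after their values were seen.

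For the search of 3' UTR words, the longest 3' UTR of each gene's protein-coding transcripts was taken from GENCODE 29 (GRCh38), which gave 10488 of 11016 genes (95.2%) with at least 50 bases, FAM13B left out. The log2 change was regressed on the presence of each 7-base word found in at least 30 genes. Trends with 3' UTR length, base composition and mean level were removed first. Residuals were limited to 1.5 log2 units, with a Bonferroni adjustment over 16327 words. Shares of genes with a word were compared by Fisher's exact test, two-sided. These steps used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.

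Each step was tested on simulated data. With 200 genes changed among 11016 in the comparison of FAM13B siRNA with scrambled siRNA, limma recovered 41.2% at a fold of 1.5, 87.5% at 2 and 99.4% at 4, and 5.95% of its calls were false. A list shifted by 0.5 log2 units was recovered while 0 of 39 others passed. A word lowering its genes by 0.1 log2 units ranked first in 10 of 10 simulations over 10488 genes. The word simulations shuffled the log2 changes among genes, which removes any link of other words to the change. They cannot show how the search ranks words where such links exist. The limma and list simulations drew noise for each gene independently, and no library was made to stand apart. In the data, lists past the threshold had estimated correlations from -0.0409 (ventricular-enriched genes) to 0.552 (cell cycle). The 0 of 39 therefore cannot show how often the preset correlation passes a list whose genes vary together. The alternatives were a replicate block, leaving out each replicate, other filters, scalings, variance models, sample weights and thresholds, and for lists an estimated correlation and fry. The fit to 6 separate columns, the design set before the data were examined, became an alternative once scrambled replicates 1 and 2 were averaged. Added after the data were seen were voom weights on the recovered reads, removal of GC and length trends and removal of genes holding GCAAGA. That removal kept the 6994 genes whose 3' UTR was searched and holds no GCAAGA, whatever their coding sequence. It thus also dropped genes not searched, FAM13B among them, so a call lost there cannot be put down to GCAAGA alone.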

Results

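Gene expression was measured by RNA sequencing in iCell cardiomyocytes, a commercial preparation of human heart muscle cells grown from induced pluripotent stem cells. The cells had received a siRNA against FAM13B or a scrambled control siRNA, each at 50 nM for 72 h. FAM13B lies at a locus associated with atrial fibrillation. The comparison asks which transcripts differ once its transcript is lowered. There were 6 samples, 3 per arm, which the series design text calls biological replicates. The tissue label reads left atrial appendage, whereas the cell type label and the culture protocol name iCell cardiomyocytes, and the samples are described here by the latter. The deposited values hold 62919022 to 90027213 reads per sample over 11017 genes. Scrambled replicates 1 and 2 differed by less than the sampling noise, with equal reads in 72.1% of genes, and were counted as 1 sample. The scrambled arm therefore has n = 2 and the FAM13B siRNA arm n = 3.

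FAM13B was lower in all 3 FAM13B siRNA samples than in every scrambled sample. Another 19 genes fell with it, among them CDK6, the G1 cyclin-dependent kinase, ZNF106, the iron exporter SLC40A1, the Z-disc protein TCAP and the sodium channel subunit SCN2B. Only 5 genes rose past the threshold, among them MYH11, the smooth muscle myosin heavy chain, the cytoskeletal linker EPPK1, the sarcoplasmic reticulum calcium buffer CASQ2 and the metallothionein MT1X. Of the 19 genes that fell beside FAM13B, 14 carry the 7-base word AGCAAGA in the 3' untranslated region (UTR), as do 18.4% of all genes searched. In total 25 of the 11016 genes tested passed an adjusted p of 0.05 in limma with Benjamini-Hochberg adjustment, 5 higher and 20 lower, with log2 changes between 0.86 and 2.11 in size.

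The targeted transcript was examined first. FAM13B (Entrez Gene 51306, chromosome 5) stood at 21.1, 15.1 and 24.8 CPM (reads scaled to library size) in FAM13B siRNA replicates 1, 2 and 3. It stood at 99.2 CPM in scrambled replicates 1 and 2 and at 74.3 CPM in scrambled replicate 3. On the log2 scale the means were 4.32 ± 0.36 (SD, n = 3) and 6.42 ± 0.29 (SD, n = 2). The log2 change of FAM13B was -2.11 with a standard error of 0.22 and a 95% interval of -2.64 to -1.58, which leaves 23.2% of the scrambled level (16.1% to 33.5%). Its adjusted p was 0.043 in limma. An exact two-sided permutation test of the group means gave p = 0.1, the smallest that the 10 splits of 5 samples allow. Without FAM13B siRNA replicate 1 the adjusted p of FAM13B was 0.23, and without scrambled replicate 3 it was 0.27, with log2 changes of -2.15 and -2.32. The related genes FAM13A and FAM13C had log2 changes of 0.27 and 0.42, with adjusted p of 0.4 and 0.43, and neither passed the threshold. Without scrambled replicate 3 FAM13C was at 0.15.

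**Figure D1:**
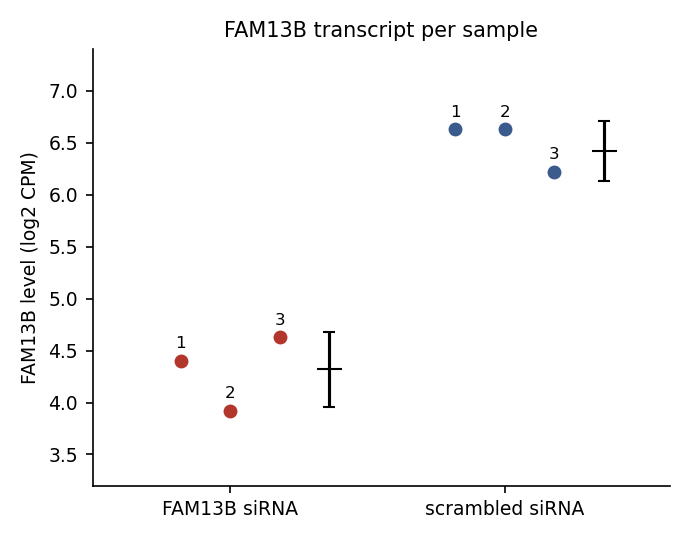
FAM13B level in each sample, in log2 CPM on the vertical axis, for the FAM13B siRNA and scrambled siRNA arms, with replicate numbers above the points and the mean ± SD as a black bar (scrambled replicates 1 and 2 counted as 1 sample). The 3 FAM13B siRNA samples lie between 3.92 and 4.63, under the scrambled samples at 6.22 and 6.63.

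Of the genes that rose and stand in the upper part of the expression range, EPPK1 showed a log2 change of 1.49 ± 0.13 (SE), a 2.82-fold rise, with adjusted p = 0.039. CASQ2 rose 2.68-fold, at log2 1.42 ± 0.17 (SE) and adjusted p = 0.043. EPPK1 and CASQ2 were higher in each FAM13B siRNA sample than in each scrambled sample. The largest rise was that of MYH11, 3.54-fold from a low level, at log2 1.83 ± 0.15 (SE) and adjusted p = 0.039. MT1X rose 2.11-fold with adjusted p = 0.049, and reads of the metallothionein family are hard to assign to 1 member. None of the 5 rising genes carries AGCAAGA in its 3' UTR, against 18.4% of all genes searched (Fisher's exact p = 0.59). So few genes cannot show a lack of the word. Of the rising genes 1, MYH11, carries the shorter word GCAAGA, as do 33.3% of all genes searched. MYH11 and MT1X lie below the expression level that the naming rule asked for and were named after their values were seen.

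Among the falling genes CDK6 was reduced the most after FAM13B, to 31.6% of the scrambled level (log2 -1.66 ± 0.21, SE, adjusted p = 0.048). The level of ZNF106 was 34.4%, that of the depalmitoylating enzyme LYPLA1 37.1%, that of SLC40A1 41.2% and that of TMEM64 41.4%. PDE4DIP, which anchors a phosphodiesterase, was at 45.9%, the NEDD8-conjugating enzyme UBE2F and the titin-binding protein TCAP were both at 48.1%, and the sodium bicarbonate cotransporter SLC4A4 was at 48.3%. Their adjusted p lay between 0.043 and 0.048. CDK6 has 3 copies of AGCAAGA in its 3' UTR, PDE4DIP and UBE2F have 2 each, and ZNF106, LYPLA1, SLC40A1, TMEM64 and SLC4A4 have 1 each, whereas TCAP carries only GCAAGA. PDE4DIP has near-identical copies on its chromosome, and its reads are uncertain to that extent.

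The other falling genes were named after their values were seen. SCN2B, the beta-2 subunit of the voltage-gated sodium channel, fell to 45.9% of the scrambled level (log2 -1.12 ± 0.13, SE, adjusted p = 0.043). Its 3' UTR, in exon 4 of 4 on chromosome 11 (GRCh38, minus strand), carries AGCAAGA at 118165383 to 118165389 and at 118163288 to 118163294. The magnesium transporter SLC41A1 and TBC1D8 were both at 51.5%, the mitochondrial nucleoside diphosphate kinase NME4 at 51.7%, HDDC2 at 45.5% and FAM168A at 40.6%, and these 5 carry the word as well. SCML1 at 33.6% and ABHD13 at 53.9% carry GCAAGA without the full word. FAM120B at 54.5% and RASD1 at 55.3% carry neither in the 3' UTR.

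**Figure D2:**
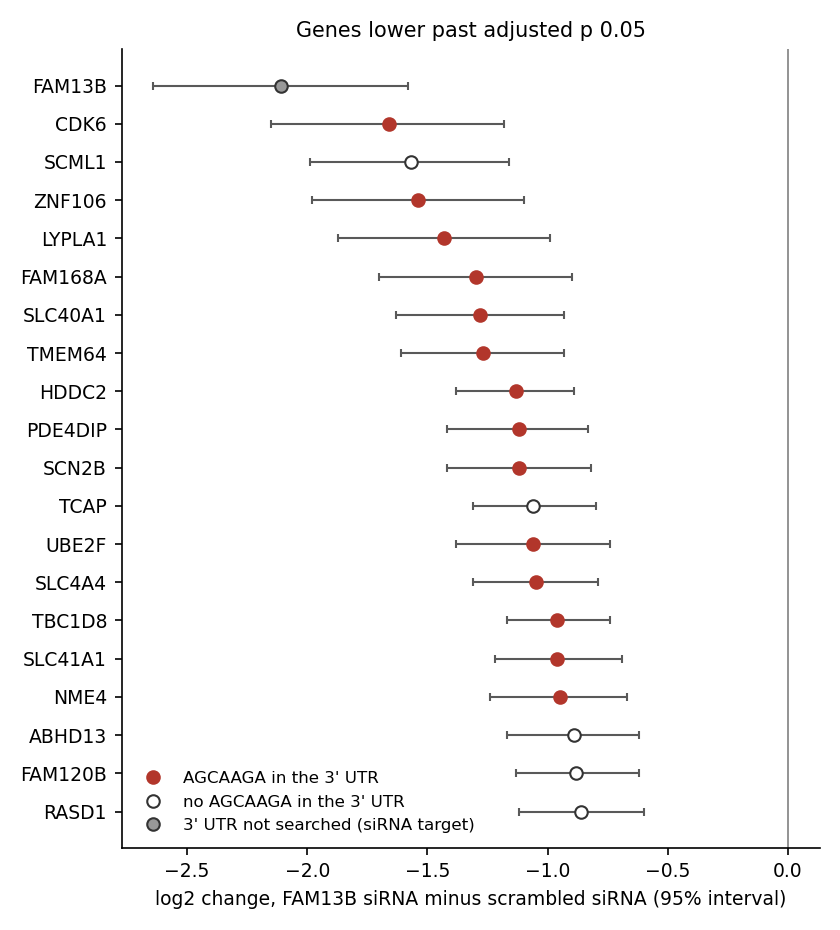
Log2 change of the 20 lower genes past adjusted p 0.05, FAM13B siRNA minus scrambled siRNA, on the horizontal axis, with 95% intervals as bars and n = 3 against 2. Filled points mark genes with AGCAAGA in the 3' UTR, 14 of the 20, and the grey point marks FAM13B, which was left out of the search.

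The association with AGCAAGA extended beyond the genes past the threshold. Among 16327 words of 7 bases in the 3' UTRs of 10488 genes, AGCAAGA went with the strongest fall, a log2 coefficient of -0.14 across its 1933 genes (z = -17.7, Bonferroni-adjusted p = 3.9e-47) after 3' UTR length, base composition and expression level were allowed for. Genes in which AGCAAGA is followed by A or T had a median log2 change of -0.15, and genes with none of the related words had 0.04. For AGCAAGA with another next base the median was -0.04. For GCAAGA without AGCAAGA it was -0.08 where A or T followed and 0.03 otherwise. The word was the strongest in FAM13B siRNA replicates 1 and 2 (z = -19.1 and -13.8) and ranked 2 in replicate 3 (z = -16.0). Each replicate was set against the same scrambled mean, so these z values are not independent. For AGCAAGA, scrambled replicate 3 against replicates 1 and 2 gave z = 1.1. The strongest word in that comparison, CTGCCCC, reached z = -7.6. A strong z thus also arises with no difference in siRNA, and the Bonferroni-adjusted p overstates certainty. Genes with the word in the coding sequence and no related word in the 3' UTR had a median of 0.00. Of these, 49.7% had a lower mean, against 40.7% of all genes with none of the words in the 3' UTR. Not all carriers fell: HSPA4L, MTHFD2, RPS3 and FAM13C carry AGCAAGA and had higher means. Genes are not independent replicates, and these values describe the libraries compared. The coding sequence of FAM13B itself holds AGCAAGA at 3 places on chromosome 5 (GRCh38, minus strand, transcript ENST00000033079.7): in exon 6 at 138011114 to 138011120, in exon 10 at 137985288 to 137985294 and in exon 13 at 137959748 to 137959754.

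**Figure D3:**
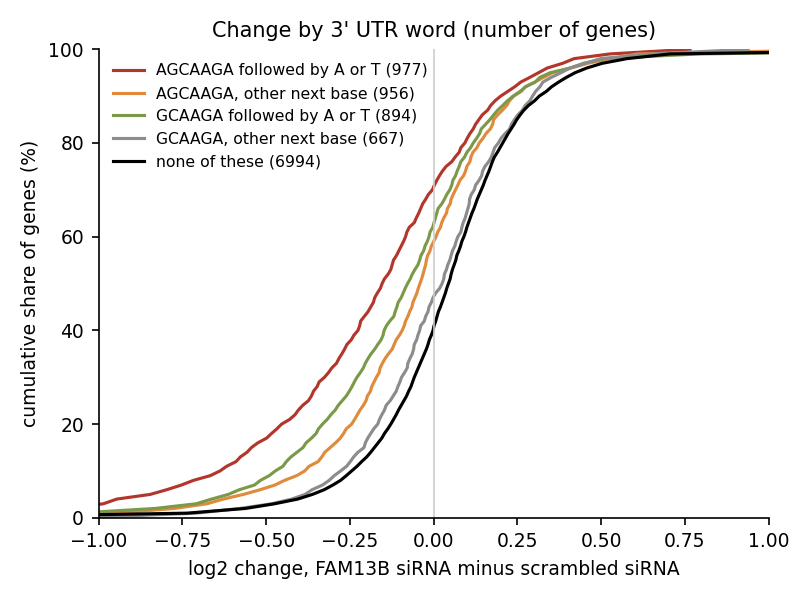
Cumulative share of genes in percent (vertical axis) against log2 change, FAM13B siRNA minus scrambled siRNA (horizontal axis, shown from -1 to 1), for genes grouped by the words in their 3' UTR. The 977 genes with AGCAAGA followed by A or T lie farthest to the left, with 70.7% below 0, against 40.7% of the 6994 genes with none of the words.

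Genes of cardiac identity showed no change past the threshold. TNNT2 had a log2 change of 0.02 (95% interval -0.27 to 0.32), MYH6 0.10 (-0.18 to 0.38), NPPA -0.04 (-0.42 to 0.34) and NPPB 0.44 (-0.07 to 0.96). The value for RYR2 was -0.18 (-0.45 to 0.10). MYH7 was at -0.44 (-0.76 to -0.12, adjusted p = 0.25) and PLN at -0.34 (-0.66 to -0.01, adjusted p = 0.35), and both were lower in each FAM13B siRNA sample than in each scrambled sample without passing the adjusted threshold. TNNT2 and MYH6 turned to -0.09 and -0.02 under quantile scaling, and NPPA to 0.12 without scrambled replicate 3. NPPB was at 0.29 without FAM13B siRNA replicate 2 and at 0.09 with sample weights. RYR2 was at -0.07 with sample weights, -0.11 with GC and length trends removed and -0.27 without scrambled replicate 3.

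Of 40 gene lists tested with camera at its preset correlation, 8 passed an adjusted p of 0.05, 4 toward higher and 4 toward lower expression. None of them held with an estimated correlation, where the smallest adjusted p was 0.69, or with fry's directional test, where it was 0.12. Fry's mixed test, which takes changes in either direction together, passed 9 lists and says nothing about a shared direction. Among them were genes at atrial fibrillation loci (mixed adjusted p = 0.041), heat shock chaperones (0.04) and ventricular-enriched genes (0.04). Interferon-stimulated genes were lower as a list (14 measured, median log2 change -0.35, adjusted p = 0.0022, and 0.69 with an estimated correlation). In that list 13 of 14 members had a lower mean and none passed the gene test, with IFIT1 at -1.44, IFI6 at -0.74, HERC6 at -0.59 and STAT2 at -0.47, of which IFIT1 and HERC6 carry GCAAGA. Without scrambled replicate 3 the median of that list was -0.15 and its adjusted p 0.052, and IFI6 was at -0.27. Genes at atrial fibrillation loci were lower as a list (45 measured, median -0.17, adjusted p = 0.0084, and 0.69 with an estimated correlation). CASQ2 was the 1 member past the threshold, and it rose. Adjusted over the list alone, CASQ2 was higher and KCNJ5 and CAMK2D were lower, with log2 changes of -0.95 and -0.60. FBXO32 was at -0.35, and KCNJ5, CAMK2D and FBXO32 carry AGCAAGA. The median of the list was -0.07 without FAM13B siRNA replicate 2 (adjusted p = 0.049) and -0.09 with sample weights (0.14), and without genes holding GCAAGA it was -0.11 (0.11).

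Ventricular-enriched genes were lower (15 measured, median -0.13, adjusted p = 0.048, and 0.69 with an estimated correlation). Adjusted over the list alone, MYL3 was higher at 0.41, and IRX3 at -0.58, IRX5 at -0.53 (-0.35 with sample weights), MYH7 and the gap junction gene GJA1 at -0.43 were lower, while 0 members passed over all genes. The list fell short of the threshold without FAM13B siRNA replicate 2 (median -0.11, adjusted p = 0.067), without replicate 3 (-0.14, adjusted p = 0.15) and without scrambled replicate 3 (-0.22, adjusted p = 0.079). It also fell short with sample weights (-0.06, adjusted p = 0.16), among genes at or above the median level (-0.09, adjusted p = 0.36), under quantile scaling (-0.10, adjusted p = 0.066) and with all 6 columns (-0.14, adjusted p = 0.051). Cell cycle genes were lower as a list (30 measured, median -0.60, adjusted p = 0.0084, and 0.82 with an estimated correlation). This list followed FAM13B siRNA replicate 2, with medians of -0.46, -1.10 and -0.01 in replicates 1, 2 and 3, and its median was -0.21 without replicate 2 (adjusted p = 0.1) and -0.27 without scrambled replicate 3 (0.57). Among genes at or above the median level the list turned to 0.05 (adjusted p = 0.62), and with all 6 columns as separate samples its median was -0.48 (adjusted p = 0.089). MCM5 was at -0.80, BUB1B at -0.89 and KIF20A at -1.02, while E2F1 was at 0.42, with 0 members past the threshold. Without replicate 2 these genes were at -0.51, -0.52, -0.50 and 0.27, and without scrambled replicate 3 MCM5 was at -0.43.

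Toward higher expression stood p53 targets (24 measured, median 0.21, adjusted p = 0.0084, and 0.69 with an estimated correlation), with BAX at 0.41, FAS at 0.63, SPATA18 at 0.45 and GDF15 at 1.68. None of these passed the gene test. Without scrambled replicate 3 the list had a median of 0.10 (adjusted p = 0.19) and FAS was at 0.37, without FAM13B siRNA replicate 2 GDF15 was at 1.05, and with all 6 columns the list had a median of 0.19 (adjusted p = 0.051). Genes of the unfolded protein and integrated stress response had a median of 0.24 (31 measured, adjusted p = 0.019, and 0.82 with an estimated correlation), with GDF15 again, ATF4 at 0.70, MTHFD2 at 0.47 and PDIA4 at 0.64. Their medians were 0.07, 0.54 and 0.05 in FAM13B siRNA replicates 1, 2 and 3, and without replicate 2 the list median was 0.01 (adjusted p = 0.15). The call was also lost with sample weights (median 0.09, adjusted p = 0.21), GC and length trends removed (0.16, adjusted p = 0.053) and genes holding GCAAGA left out (0.26, adjusted p = 0.11). Heat shock chaperones had a median of 0.25 (16 measured, adjusted p = 0.046, and 0.69 with an estimated correlation). HSP90AA1 at 0.74, HSPA4L at 0.45 and HSPB1 at 0.35 were higher and CHORDC1 at -0.55 was lower when adjusted over the list alone, which counted 7 higher and 2 lower against 0 over all genes. HSPA4L holds 3 copies of AGCAAGA and CHORDC1 1 copy. The list lost its call without FAM13B siRNA replicate 2 (median 0.12, adjusted p = 0.12) and without replicate 3 (median 0.28, adjusted p = 0.096). It also lost it with all 6 columns (median 0.26, adjusted p = 0.051), GC and length trends removed (median 0.25, adjusted p = 0.076), sample weights (median 0.15, adjusted p = 0.24) and genes holding GCAAGA left out (median 0.27, adjusted p = 0.06). Cytosolic ribosomal proteins had a median of 0.11 (67 measured, adjusted p = 0.0084, and 0.87 with an estimated correlation), 56 of 67 with a higher mean. RPSA was at 0.38, RPL34 at 0.27 and RPS3 at 0.24, whereas RPS24 was at -0.78, and all of these families have processed pseudogenes that can share reads. Without FAM13B siRNA replicate 3 the adjusted p of the ribosomal list was 0.22 (median 0.07), with sample weights 0.26 (median 0.07) and without genes holding GCAAGA 0.13 (median 0.09).

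**Figure D4:**
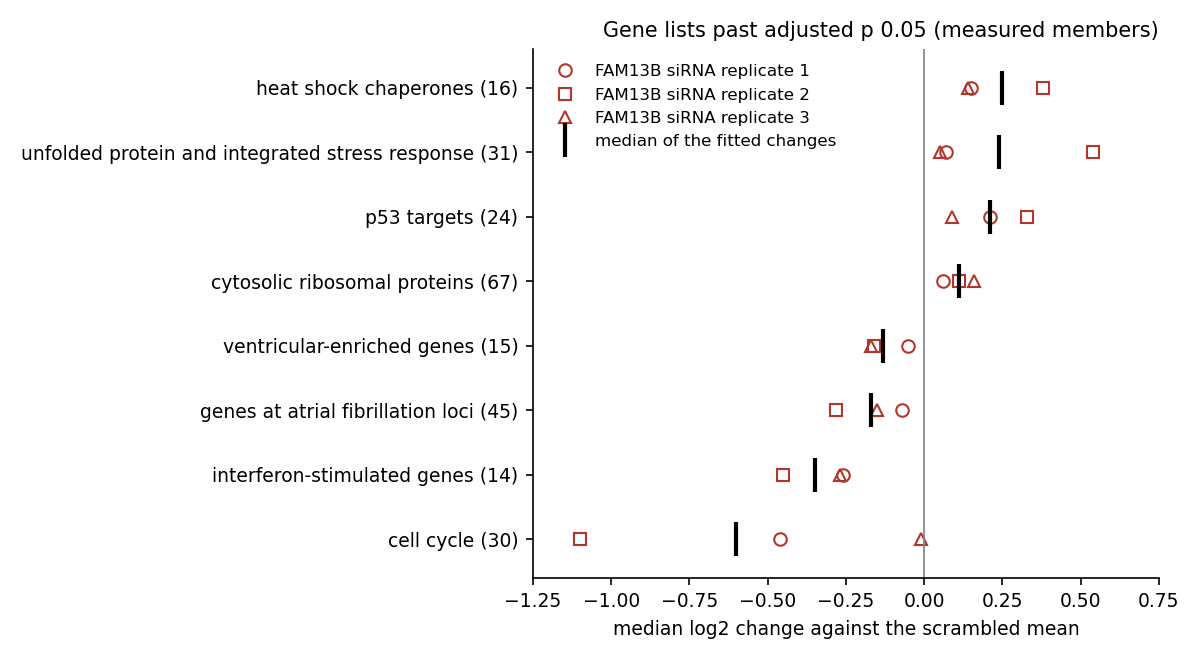
Median log2 change of the 8 gene lists past adjusted p 0.05 (camera, preset correlation) on the horizontal axis, with the number of measured members in brackets, open symbols for each FAM13B siRNA replicate against the scrambled mean and a bar for the median of the fitted changes. The cell cycle list runs from -1.10 in replicate 2 to -0.01 in replicate 3.

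Among all tested genes the median log2 change was 0.01, and 1542 genes had an unadjusted limma p under 0.05, 665 higher and 877 lower, where chance gives 551. The arms did not overlap in 4000 genes, 36.3% of those tested, where chance gives 20%. FAM13B siRNA replicate 2 stood apart on the first principal component, which took 65.7% of the variance, at -34 against -3.36 and 4.84 for replicates 1 and 3 and 15 and 17.5 for the scrambled arm. The second component took 17.3% and separated the remaining FAM13B siRNA samples from the scrambled ones. The count of 25 genes became 0 in limma without FAM13B siRNA replicate 1 or without scrambled replicate 3 (1069 and 698 genes at an unadjusted p under 0.05) and 318 without FAM13B siRNA replicate 2. It was 1 without a variance trend, 14 with robust variance, 1569 with sample weights (707 higher and 862 lower) and 102 with GC and length trends removed. It was 452 with all 6 columns as separate samples. Among the 6994 genes searched and without GCAAGA in the 3' UTR it was 0 (778 at an unadjusted p under 0.05). That fit also lacks FAM13B and the other genes not searched. In that last fit the log2 changes stayed the same, as for EPPK1 at 1.49 and RASD1 at -0.86. Their limma adjusted p moved to 0.066 and 0.11, so the 0 does not show that these changes depend on GCAAGA.

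**Figure D5:**
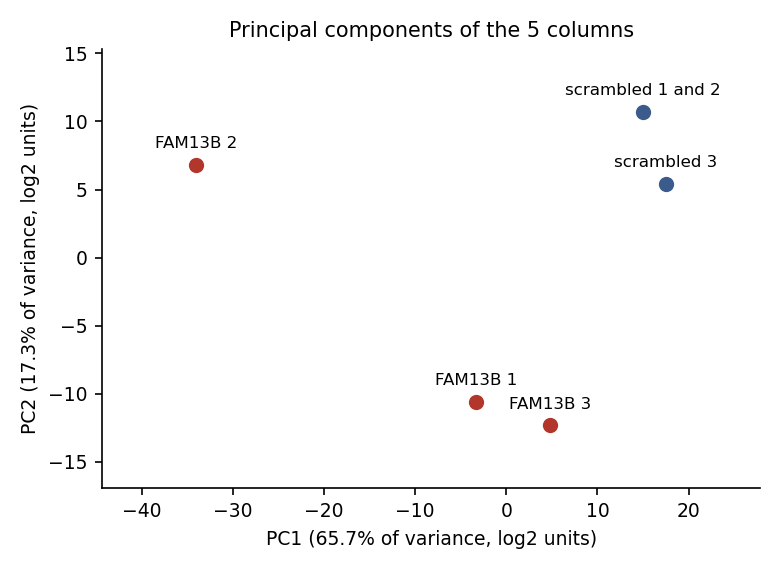
Positions of the 5 columns on the first (horizontal, 65.7% of variance) and second (vertical, 17.3%) principal components of the log2 values, in red for FAM13B siRNA and blue for scrambled siRNA, with replicate numbers beside the points. FAM13B siRNA replicate 2 lies at -34 on the first component, away from the other 4 columns.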

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

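The fit to 6 separate columns was the design set before the data were examined, and averaging scrambled replicates 1 and 2 departed from it. Voom weights, removal of GC and length trends and removal of genes holding GCAAGA were tests chosen after the data were seen. Removal of genes holding GCAAGA in the 3' UTR also dropped genes whose 3' UTR was not searched, FAM13B among them. With 3 samples against 2 the count of changed genes moves with single libraries, while depth limits little, since the median gene has at least 2095 reads in a sample. The count of 25 genes past adjusted p 0.05 (5 higher, 20 lower) compares with at most 0 in any other of the 10 splits of the 5 samples, and 1 split, the real one, gave as many, which is too few splits for a share under 0.05. It stayed within 1.5 times under voom weights (26), median scaling (26), quantile scaling (21), genes at or above the median level (20) and a log2 change of at least 1 (19). Leaving the filter out adds 1 gene, so the count of 25 there says nothing about stability. Pseudocounts apply to linear values only and were not run. DESeq2 and edgeR were not run either, since the deposited unit is log2, and voom on the recovered whole reads was run in their place. Without scrambled replicate 3 the lone scrambled sample is assumed to vary like the other arm. Sample weights ran from 5.97 to 0.192, and their estimate stopped before it converged. Where a value changed, the cause was not tested, except for the looser threshold, which passes more genes by construction.

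In leave-one-out fits the count ran from 0 to 318, with 0 to 89 higher and 0 to 229 lower. The count was 0 without FAM13B siRNA replicate 1 and without scrambled replicate 3 (limma, 1069 and 698 at an unadjusted p under 0.05), and 35 without FAM13B siRNA replicate 3. It was 1 without a variance trend (MYH11, 1 higher and 0 lower, 1491 unadjusted), 14 with robust variance (3 and 11), 1569 with sample weights (707 and 862) and 55 at adjusted p 0.1 (16 and 39). All 6 columns as separate samples gave 452 (168 and 284) and removal of GC and length trends 102 (24 and 78). The 6994 genes searched and without GCAAGA in the 3' UTR gave 0 in limma (0 higher and 0 lower, 778 unadjusted). EPPK1 and RASD1 among them kept their log2 changes. With the replicate number as a block over all 6 columns it was 296 (87 and 209). Deviations of same-numbered samples from their arm means correlated at 0.15, 0.11 and 0.26, all over 0.1, but scrambled replicates 1 and 2 are in effect 1 library, so these are not 3 independent pairs, and FAM13B siRNA replicates 1 and 2 correlate equally with both. The numbers were therefore not taken to pair the samples. Of the lists, the block moved heat shock chaperones to an adjusted p of 0.055 and ended no other list call. The log2 change of FAM13B ran from -2.32 to -1.91 in leave-one-out fits and passed in 14 of 17 alternatives. It fell short at -2.11 without a variance trend (adjusted p = 0.074), and without FAM13B siRNA replicate 1 or scrambled replicate 3.

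The 8 lists past the threshold became 4 to 15 in leave-one-out fits, 5 among genes at or above the median level, 3 with sample weights, 4 with all 6 columns and 5 without genes holding GCAAGA. The count was 0 with an estimated correlation and with fry's directional test (unadjusted counts at p under 0.05: 0 and 6). For named genes other than FAM13B, 1320 values kept direction and side of the threshold, 141 passed it anew, 99 fell short and 9 turned. For lists the same counts were 603, 12, 45 and 51, with direction read from the sign of the median. That reading replaced the direction of the list test, by which 41 turned, after both had been computed, and 71 turned by either reading, 1 of them in a list past the threshold (cell cycle). MYH6 turned to -0.02 under quantile scaling, TNNT2 to -0.09 there and to -0.03 with GC and length trends removed, and NPPA to 0.02 under the block and with all 6 columns. Under the block, glycolysis, epicardial and epithelial markers and autophagy turned to 0.01, and with all 6 columns these lists gave 0.01 as well. Quantile scaling turned TGF-beta targets to 0.01, autophagy to 0.00 and glycolysis to 0.03, and removal of GC and length trends turned TGF-beta targets to 0.03. With sample weights the turned medians were TGF-beta targets 0.01, cardiac stress and fetal programme -0.02, proteasome 0.00, mitochondrial DNA-encoded genes -0.01, inflammatory cytokines 0.08, respiratory chain -0.05, epicardial and epithelial markers 0.03, fatty acid oxidation -0.04, cholesterol biosynthesis 0.00 and hypoxia response -0.09. Among genes at or above the median level they were hypoxia response -0.02, gap junction and intercalated disc -0.03, fatty acid oxidation -0.02 and cell cycle 0.05. Without genes holding GCAAGA they were glycolysis 0.06, fatty acid oxidation -0.01, fibroblast markers 0.03 and inflammatory cytokines 0.06. Leave-one-out values that crossed 0 ran from -0.02 to 0.13 for MYH6, -0.13 to 0.12 for NPPA, -0.04 to 0.09 for TNNT2, -0.02 to 0.08 for SRF and MRTF targets, -0.02 to 0.07 for TGF-beta targets, -0.04 to 0.03 for autophagy, -0.03 to 0.10 for cardiac stress, -0.09 to 0.14 for epicardial markers, -0.04 to 0.09 for fatty acid oxidation, -0.13 to 0.01 for fibroblast markers, -0.10 to 0.02 for gap junction genes, -0.05 to 0.10 for glycolysis, -0.05 to 0.11 for hypoxia response, -0.16 to 0.10 for inflammatory cytokines and -0.02 to 0.13 for the respiratory chain.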

Other observations

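The tests of explanations in this part, other than the search for 3' UTR words, were chosen after the results were seen, the list tests were fixed before the data were examined, and the word search was chosen after the list of changed genes was known and before it was run. The genes named in this first paragraph were chosen after their values were seen, because they pass an adjusted p of 0.05 over a fixed list alone, and none of them passes over all genes. The gap junction and intercalated disc list had a median of 0.02 (camera adjusted p = 0.31), and 8 of its 17 measured genes had a lower mean. Over that list alone 4 genes passed, all lower. The desmosomal gene PKP2 had a log2 change of -0.94, CXADR -0.84, NRAP -0.81 and GJA1 -0.43. PKP2 and GJA1 carry GCAAGA in the 3' UTR, as do 33.3% of all genes searched, and CXADR and NRAP do not. In the glycolysis list, with a median of 0.00 (adjusted p = 0.54), SLC2A1, the main glucose transporter of many cells, was at -0.87 (adjusted p = 0.06 over all genes), ALDOC at -1.57 and PGAM2 at -0.56, of which SLC2A1 carries AGCAAGA and PGAM2 was not searched. The hypoxia list, with a median of 0.05 (adjusted p = 0.71), shared SLC2A1 and added ADM at -0.67 and INSIG2, which carries AGCAAGA, at -0.74. Fibroblast markers went both ways, with S100A4 at 1.08, POSTN at 0.96 and MFAP5 at 0.86 higher and VIM, which carries AGCAAGA, at -0.91. The sodium channel subunit SCN4B was at 0.74. The calcium-handling gene HRC was at -0.60, the skeletal actin gene ACTA1 at 1.26 and the smooth muscle gene CNN1 at 0.59. Targets of insulin and FOXO signalling included TXNIP at -0.71 and INSR at -0.39, and YAP1 of the Hippo pathway was at -0.63, of which INSR and YAP1 carry AGCAAGA.

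Of the 32 lists that did not pass, neural markers had the highest median at 0.53 (5 measured, adjusted p = 0.081) and pacemaker and conduction genes the lowest at -0.50 (10 measured, adjusted p = 0.081). Smooth muscle and pericyte markers had a median of 0.20 (13 measured, adjusted p = 0.081), with MYH11 and CNN1 higher over the list alone. Mitochondrial DNA-encoded genes had a median of 0.25, with -0.03, 0.71 and 0.07 in FAM13B siRNA replicates 1, 2 and 3. Sarcomere genes had a median of -0.07, calcium handling -0.11, potassium channels -0.15, sodium channels -0.19, cardiac transcription factors -0.09 and atrial-enriched genes -0.09. The 13 measured genes of the microRNA and siRNA machinery had 0.06 (adjusted p = 0.82). In the search of 3' UTR words no word went with a rise past the adjusted threshold, the strongest being CCCTGGC at z = 4.3.

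The first pattern weighed is that 20 of the 25 genes past the threshold fell. A candidate explanation is that the FAM13B siRNA silenced other transcripts through matches of its seed in their 3' UTRs: AGCAAGA gave z = -17.7, and 25.0% of all words occur in the FAM13B transcript, so its 3 copies there weigh little. Against base composition as the cause, 0 of 102 words made of the same letters and not sharing GCAAG with it gave a fall as strong, the strongest at z = -4.8, while GCAAGAA and AAGCAAG, which share GCAAG and were left out, reached -16.9 and -10.1. Against loss of FAM13B acting without such sites, the strongest word was picked again with the 24 genes past the threshold left out. It was AGCAAGA again (z = -17.0, with 3' UTR length allowed for). The word was found in 73.7% of the 19 falling genes left out and 18.3% of the other genes (odds ratio 12.5, Fisher's exact p = 2.3e-07, in the same libraries). These shares make no allowance for 3' UTR length, which ran from 207 bases (TBC1D8) to 10222 (CDK6) among the falling carriers. The shares alone therefore cannot separate the word from length. No single falling gene can be assigned to silencing through such sites or to loss of FAM13B. The reason is that 1 siRNA was used and its sequence is not given in the sources used here. For RASD1 and FAM120B, the 2 falling genes without GCAAGA in the 3' UTR, loss of FAM13B itself and indirect effects cannot be told apart either. Of these 2, 1 carries AGCAAGA in its coding sequence, and silencing through that site stays open as well. TCAP carries GCAAGA followed by neither A nor T. Genes of that kind without AGCAAGA had a median log2 change of 0.03, against 0.04 for genes with none of the words.

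The second pattern is the near identity of scrambled replicates 1 and 2. A set of reads counted and deposited under both names is consistent with the chi-square of 0.00541 per degree of freedom, since separate sequencing of even 1 library gives about 1. The same value argues against libraries from separate cultures, which in the other pairs of an arm gave at least 58.8. How the reads of the remaining genes came to differ slightly stays open. No biological explanation was tested.

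The third pattern is the distance of FAM13B siRNA replicate 2 from the other libraries. A trend with GC content and transcript length took 23.9% of the variance of its difference from replicates 1 and 3, which argues against that trend as the whole cause. Between replicates 1 and 3 such a trend took 33.2% of the variance, so replicate 2 is not alone in showing one. These differences had SDs of 0.37 and 0.195 log2 units, so the shares are of unlike totals. In log2 units the smaller share is the larger trend, that of replicate 2. A scrambled library under the wrong label is argued against by its FAM13B level of 15.1 CPM, below every scrambled sample. Its list medians included -1.10 for cell cycle genes, 0.84 for neural markers, 0.71 for mitochondrial DNA-encoded genes and 0.54 for stress response genes, and neither a different state of that culture nor its RNA quality was tested.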
